A study of Mus musculus with 8 samples.

How the data were processed

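Gene expression in the testes of C57BL/6 mice was compared between 4 libraries of mice given an antibody against PD-L1 and 4 libraries of mice given an IgG2b isotype control. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with TRIzol, treated with DNase I and made into libraries with the Illumina TruSeq RNA kit. The deposited table gives TPM per gene, with a column for each of the 8 libraries, columns of group means and a gene length column, per the file headers. The deposited length column holds a gene length and was used only for a check of length trends and for the overlap of a pair of genes. The submitters' processing notes name CASAVA 1.8, HISAT2, StringTie and RSEM and the genome build mm10. The role and order of these tools, the annotation release, the strand setting and any filters are not given in the sources used here. TPM in each library summed to 1000000 and keeps no depth, so depth is unknown, and no intervals or floors that need counts are given. The TPM scale means that a rise in abundant transcripts lowers all others.

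The table held 57690 rows, of which 55536 carried Ensembl gene identifiers and 2154 were loci with assembler names and no gene symbol. Of the Ensembl identifiers 55450 (99.8%) matched GENCODE release M21 for GRCm38, the assembly also called mm10, which gave coordinates, biotypes and GC content. Gene symbols were those of the deposited table. The deposited group means equalled the means of the 4 libraries and were not used as samples. No pair of libraries held the same values: at most 1.05% of genes with a value had equal TPM in a pair.

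Analyses were run in R 4.3.3 with limma 3.58.1 and in Python 3.11.15. Values were transformed to log2(TPM + 1), with a pseudocount of 1, and genes with a mean of at least 1 TPM over the 8 libraries were tested, 20343 in all. The limma model had an intensity trend, a group term and no covariates, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. The table held TPM as the design assumed, so the design was used as written before the data were examined. The 26 gene lists were also fixed at that time, and lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01. Camera compares a list with all other genes, and fry tests whether a list's genes move, on balance, one way. Single values were compared with two-sided exact permutation tests over 70 assignments, whose smallest p is 0.0286. Where several rows shared a symbol, the row with the highest mean was used.

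Named genes followed a rule fixed before the data were examined. It took Cd274 and Pdcd1, then 6 genes with higher and 6 with lower values whose groups did not overlap, chosen by size of change among genes past the threshold and filled by smallest unadjusted p where too few passed. Only genes with a proper symbol qualified, and 1 gene that the rule took is not reported here. It also took from each list of immune, germ cell and somatic testis genes the 2 members with the smallest p, and from each list of other cell types and stress responses 1 member.

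The test was tested on simulated data in which 200 of 20343 genes were changed in the comparison of anti-PD-L1 with IgG. Of genes changed by 2 on the log2 scale 96% were recovered, and of those changed by 1 71%, with 4 unchanged genes called. The simulated noise was independent between genes, without the structure that the real libraries share, and many changes at once ease the adjustment. These shares therefore check the code and do not give the power in the real data. In the real data the median standard error of a log2 difference was 0.14.

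Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a filter of 5 TPM, quantile normalization, rescaling with TMM factors (30% of M and 5% of A values trimmed), array quality weights, no intensity trend, the replicate number as a block, each library left out, an estimated correlation in camera, and fry. Chosen after seeing the data were leaving out both libraries that stand apart, a covariate for them, rescaling over protein-coding genes, removal of a smooth GC and length trend (splines with 5 degrees of freedom), exact permutation of list means, a test of Gene Ontology terms, and an estimated correlation in camera under each of the refitted alternatives. Tests that set the libraries that stand apart and the GC and length trend against the lower elongating spermatid genes were written and run as well, and their values are given only among the alternatives. Count-based tests were not used here, since the values are not counts.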

Results

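Bulk RNA was sequenced from the testes of C57BL/6 mice aged 8 weeks that had received 2 intraperitoneal doses of 200 µg of either an antibody against PD-L1 or an IgG2b isotype control. PD-L1 is the ligand of the T cell inhibitory receptor PD-1, and antibodies against it are used to release T cells from that inhibition. Tissue was taken 7 days after treatment, and each group held 4 libraries. Values are in TPM, a unit of transcript abundance scaled to gene length and to the library total, so each library summed to 1000000 and its read depth is unknown. Fold changes are on the scale of log2(TPM + 1), which understates the change of genes with low values. The labels do not say that the 4 libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

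The series asks how anti-PD-L1 changed the transcripts of the testis. Insl3, which encodes the peptide hormone INSL3 of Leydig cells, was the most abundant of the genes named for their difference: it was at 874 ± 106 TPM in IgG libraries and at 2210 ± 656 TPM in anti-PD-L1 libraries (SD, n = 4). Transcripts of elongating spermatids, the late germ cells that compact their chromatin with protamines, were lower on average, and markers of adipocytes were lower by a wider margin, a mean log2 difference of -0.87, or -0.45 without IgG replicate 1. Both lists passed in limma's camera at its preset correlation, and both calls were lost at adjusted p = 0.90 with an estimated correlation (Benjamini-Hochberg over the lists) and also with fry. Too few markers of T cells and B cells were measured for a list test, and macrophage markers formed no group that passed. Genes of antigen presentation and interferon-stimulated genes did not pass in the test as designed. The first passed under 5 alternatives, some of which kept all 8 libraries, and the second under 2 that left out anti-PD-L1 replicate 1. Those calls were lost as well with an estimated correlation, at adjusted p from 0.73 to 0.91 in limma camera with Benjamini-Hochberg adjustment. No single gene passed the test over all genes.

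Cd274, the gene of PD-L1 itself (mm10 chromosome 19, 29367455 to 29388095), was at 0.978 ± 0.0929 TPM in IgG libraries and at 1.21 ± 0.229 TPM in anti-PD-L1 libraries (SD, n = 4). Its log2 difference was 0.15 with a 95% confidence interval from -0.18 to 0.49, and a two-sided exact permutation test over the 70 assignments of the libraries gave p = 0.114. An antibody against the protein need not change the transcript, so this value does not check the labels. Pdcd1, the gene of PD-1, was near the floor of the table in both groups, at means of 0.0575 and 0.07 TPM, and was not tested.

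Of 20343 genes tested with limma, 0 passed a Benjamini-Hochberg adjusted p of 0.05, and the smallest adjusted p was 0.0738. An unadjusted p under 0.05 was reached by 1063 genes, 611 higher and 452 lower after anti-PD-L1, where chance alone gives about 1017. After quantile normalization the same split was 524 higher and 596 lower, with TMM rescaling 411 and 471, and after removal of a GC and length trend 438 and 430. Without IgG replicate 4 the count at an unadjusted p under 0.05 was 1861, 1281 higher and 580 lower. It was 2009, 1337 higher and 672 lower, without both that library and anti-PD-L1 replicate 1, and 2155, 1371 higher and 784 lower, with array quality weights. The 4 anti-PD-L1 libraries lay entirely above the 4 IgG libraries for 358 genes and entirely below for 251, together 2.99% of the genes, where chance gives 2.86%. Without IgG replicate 4 the count of genes past the threshold was 15, without anti-PD-L1 replicate 4 it was 3, and it was 1 without IgG replicate 2 and 1 without anti-PD-L1 replicate 1. A pseudocount of 0.1 gave 1 gene and array quality weights gave 5.

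Among named genes with higher values and no overlap between the groups, none passed. Tomm20, a receptor of the mitochondrial import machinery, was at 19.7 ± 5.23 TPM in IgG libraries and at 46.9 ± 6.57 TPM in anti-PD-L1 libraries, a log2 difference of 1.23 (SE 0.17). Tsen34, a subunit of the tRNA splicing endonuclease, differed by 0.75 (SE 0.11), and Klhl15, an adaptor of a CUL3 ubiquitin ligase, by 0.65 (SE 0.10). Med9, a subunit of Mediator, differed by 0.59 (SE 0.09), and Rnaset2a, a ribonuclease gene with a near-identical copy in Rnaset2b that makes its own value uncertain, by 1.05 (SE 0.17). Adjusted p was 0.202 for Insl3, Tomm20, Tsen34 and Klhl15 and 0.25 for Med9 and Rnaset2a in limma with Benjamini-Hochberg adjustment. Tomm20 passed without IgG replicate 4 and with array quality weights, Tsen34 with array quality weights, and Rnaset2a without IgG replicate 4.

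Named genes with lower values did not pass either, with adjusted p from 0.468 to 0.653 in limma with Benjamini-Hochberg adjustment. Lgalsl, a galectin-like gene, was at 11.7 ± 6.08 TPM in IgG libraries and at 2.54 ± 1.32 TPM in anti-PD-L1 libraries, a log2 difference of -1.80 (SE 0.34). Taf12, a subunit of the general transcription factor TFIID, differed by -0.48 (SE 0.10). Teddm2 differed by -0.94 (SE 0.22), and Sharpin, part of the linear ubiquitin assembly complex, by -0.25 (SE 0.06). Pdcd5-ps, a processed pseudogene that can share reads with its parent gene, differed by -0.67 (SE 0.15). Outside the rule for named genes, and chosen after their values were seen, Gm49462 and Gm9887 had the smallest adjusted p. Gm49462, a long noncoding RNA, was at 10.1, 8.25, 5.11 and 3.19 TPM in the IgG libraries and was listed at 0 in all 4 anti-PD-L1 libraries. Gm9887 was listed at 0 in 3 IgG libraries and at 0.95 TPM in the other, and ranged from 5.64 to 19.1 TPM in the anti-PD-L1 libraries.

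Leydig cells, the steroid-producing cells between the tubules, were represented by 19 tested genes, of which 8 were higher and 11 lower. None of the 19 passed over all genes, while 2 of 19 passed adjusted over the list alone, Insl3 at 0.0017 and Fdx1 at 0.0289 in limma with Benjamini-Hochberg adjustment. That adjustment was made within each of the 26 lists and does not allow for the number of lists. Insl3 was higher by 1.30 on the log2 scale (SE 0.19), and its libraries ranged from 751 to 998 TPM in the IgG group and from 1610 to 3028 TPM in the anti-PD-L1 group. Fdx1, the ferredoxin that passes electrons to mitochondrial steroidogenic enzymes, was at 35.8 ± 5.65 TPM and at 53.5 ± 8.70 TPM, a log2 difference of 0.57 (SE 0.14). The steroidogenic genes Star, Cyp11a1 and Cyp17a1 differed by -0.26, -0.04 and -0.06, each with an unadjusted p above 0.05, and 3 genes of the list were under it. The list had a median of -0.008 and a mean of 0.09, and camera placed it upward with an adjusted p of 0.60 (limma camera, Benjamini-Hochberg over the lists). Insl3 lies on chromosome 8 of mm10, 71689214 to 71690575, within the span of Jak3, 71676296 to 71690575, on the same strand, so reads of the shared part cannot be assigned with certainty. Jak3 was at 5 ± 0.0931 TPM in IgG libraries and at 5.02 ± 0.426 TPM in anti-PD-L1 libraries.

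**Figure D1:**
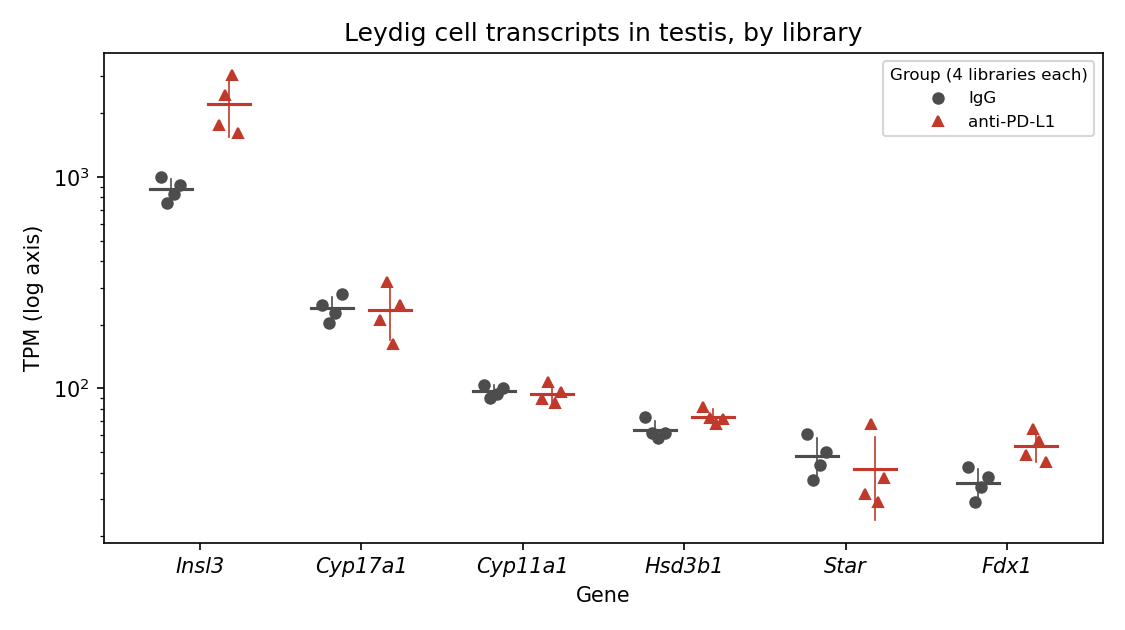
Expression in TPM on a log axis of 6 Leydig cell genes in each of the 8 testis libraries, with group means as horizontal lines and SD as vertical lines. Insl3 lay between 751 and 998 TPM in the IgG libraries and between 1610 and 3028 TPM in the anti-PD-L1 libraries, and Cyp11a1 and Cyp17a1 overlapped between the groups.

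Along the germ cell series, the list mean was lower for the late stage and higher for the early stage, with libraries overlapping between the groups. Exact permutation of list means over members with a mean above 0 TPM gave p = 0.171 for elongating spermatids and p = 0.143 for spermatogonia. Of 24 elongating spermatid genes, 22 were lower and 2 higher, with a mean log2 difference of -0.09, and the list fell in camera (adjusted p = 4.2e-06, limma camera, Benjamini-Hochberg over the lists). The call was lost at adjusted p = 0.90 with an estimated correlation. Prm1 and Tnp1, which encode a protamine and a transition protein, differed by -0.21 and -0.21 on the log2 scale. They went from 15628 to 13478 TPM and from 14073 to 12142 TPM. After quantile normalization they differed by -0.02 and -0.05, and the mean of the list was -0.05. That method gives genes of equal rank the same value in each library, which narrows differences of the most abundant genes by construction. These smaller values therefore cannot show whether the difference depends on scaling. Of 18 spermatogonia markers, 12 were higher and 6 lower, with a mean of 0.11, or 0.18 without IgG replicate 4 and anti-PD-L1 replicate 1, and the list rose in camera (adjusted p = 0.042, limma camera, Benjamini-Hochberg over the lists). That call was lost at adjusted p = 0.90 with an estimated correlation, and also without IgG replicate 1, 2 or 3, without anti-PD-L1 replicate 2 or 4, and with a filter of 5 TPM. Id4, a marker of spermatogonial stem cells, differed by 0.40 (SE 0.14) and Upp1 by 0.39 (SE 0.17), or by 0.69 with a pseudocount of 0.1. Meiotic spermatocyte genes were higher in 21 of 32, with a mean of 0.05, and round spermatid genes in 18 of 23, with a mean of 0.06, and neither list passed, with adjusted p of 0.29 and 0.26 in limma camera with Benjamini-Hochberg adjustment. The round spermatid list passed without anti-PD-L1 replicate 1, with a mean of 0.09 (adjusted p = 0.0084, limma camera, Benjamini-Hochberg over the lists), a call lost at adjusted p = 0.91 with an estimated correlation. Mybl1, a transcription factor of pachytene spermatocytes, differed by 0.17, or by 0.09 after removal of a GC and length trend, Spata22 by 0.25, and the acrosomal genes Spaca1 and Lyzl6 by 0.30 and 0.17. Spaca1 differed by 0.19 without IgG replicate 2. In each of these 4 lists 0 genes passed in limma, adjusted over the list alone or over all genes, and 4, 4, 1 and 2 genes of the elongating, spermatogonia, meiotic and round lists had an unadjusted p under 0.05.

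Most fixed markers of lymphocytes were below the filter. Only 4 of 25 T and NK cell markers and 2 of 16 B and plasma cell markers had a mean of at least 1 TPM, too few for a list test. Cd3d differed by -0.31, Trbc2 by -0.15, Pax5 by -0.17 and Ighm by -0.18, and all 4 moved with single libraries. Without IgG replicate 1 Ighm differed by 0.01 and Trbc2 by -0.03, and without IgG replicate 2 Trbc2 differed by -0.28 and Pax5 by -0.08. Trbc2 differed by -0.06 without IgG replicate 3, by -0.08 without anti-PD-L1 replicate 3 and by -0.10 without anti-PD-L1 replicate 4. Cd3d differed by -0.49 without IgG replicate 4, and Pax5 by -0.25 without anti-PD-L1 replicate 1. List means were also taken over members with a mean above 0 TPM, tested or not. These were 24 T and NK and 15 B and plasma markers, with differences of -0.02 and -0.04. Exact permutation of these list means gave p = 0.657 for the T and NK list and p = 0.257 for the B and plasma list. Of 14 macrophage and myeloid markers 10 were higher, with a mean of 0.05, or -0.005 without anti-PD-L1 replicate 1, and an adjusted p of 0.60 in limma camera with Benjamini-Hochberg adjustment. Within that list Aif1 was at 520 and 481 TPM and the complement gene C1qb at 16.4 and 18.4 TPM in the IgG and anti-PD-L1 groups. Aif1 was thus far above C1qb, and Cd3d was at 42 and 33 TPM while most T and NK cell markers were below the filter. Bulk RNA does not show which cells held these transcripts, so they need not reflect immune cells.

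Of 15 genes of MHC and antigen presentation 13 were higher, with a mean of 0.20, and the list did not pass, at an adjusted p of 0.14 in limma camera with Benjamini-Hochberg adjustment. By limma camera with Benjamini-Hochberg adjustment it passed with TMM rescaling (adjusted p = 0.047), with the replicate block (0.019) and after removal of a GC and length trend (0.032). By the same test it passed without IgG replicate 1 (mean 0.28, 0.0060) and without anti-PD-L1 replicate 3 (mean 0.31, 0.011). With an estimated correlation these calls were lost, at adjusted p from 0.76 to 0.91, and the mean was 0.03 without anti-PD-L1 replicate 1 and 0.04 without both libraries that stand apart, IgG replicate 4 and anti-PD-L1 replicate 1. Its class II members Cd74 and H2-Aa differed by 0.74 (SE 0.34) and 0.69 (SE 0.38), and without anti-PD-L1 replicate 1 these were 0.39 and 0.29. Of 16 interferon-stimulated genes 9 were higher and 7 lower, with a median of 0.02 and a mean of -0.04, and camera placed the list downward with an adjusted p of 0.60 (limma camera, Benjamini-Hochberg over the lists). Without anti-PD-L1 replicate 1 that list passed, with a mean of -0.14 (adjusted p = 0.038, limma camera, Benjamini-Hochberg over the lists), a call lost at adjusted p = 0.91 with an estimated correlation. Xaf1 differed by -0.57 (SE 0.15) and Gbp3 by 0.35 (SE 0.18), or by 0.65 with a pseudocount of 0.1. Of 7 inflammatory cytokines and chemokines 5 were higher, and the median and mean were 0.02 and 0.07 while camera placed the list downward, with an adjusted p of 0.86 (limma camera, Benjamini-Hochberg over the lists). The mean was -0.07 without anti-PD-L1 replicate 1. Il18 differed by -0.34, and by -0.55 to -0.18 over the alternatives, the weakest without anti-PD-L1 replicate 3. The chemokine Ccl8 differed by 0.94, or by 0.36 without anti-PD-L1 replicate 1 and 0.58 without IgG replicate 2. Of 6 immune checkpoint genes 5 were higher, among them Vsir by 0.28, or by 0.14 without anti-PD-L1 replicate 1 and 0.45 without anti-PD-L1 replicate 3, with a mean of 0.08 and an adjusted p of 0.55 in limma camera with Benjamini-Hochberg adjustment. In all 7 immune lists 0 genes passed in limma, adjusted over the list alone or over all genes. In the macrophage list 1 gene, Aif1, and in the interferon-stimulated list 1 gene had an unadjusted p under 0.05.

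Sertoli cells, which nurse the germ cells, did not move as a group by the test: 15 of 21 markers were higher, with a mean of 0.03 and an adjusted p of 0.65 in limma camera with Benjamini-Hochberg adjustment. Amh differed by 0.32 (SE 0.18), or by 0.21 without anti-PD-L1 replicate 1 and 0.09 after removal of a GC and length trend. Sox9 differed by 0.12 (SE 0.12), or by 0.07 without IgG replicate 1, 0.20 without IgG replicate 4 and 0.25 without both libraries that stand apart. Junction genes of the blood-testis barrier were higher in 9 of 18, with a median of -0.0004 and a mean of 0.001, and camera placed them downward with an adjusted p of 0.60 (limma camera, Benjamini-Hochberg over the lists). Nectin2 and Cldn5 differed by -0.14 and -0.15, and Nectin2 by -0.22 after removal of a GC and length trend. Apoptosis and p53 target genes were higher in 10 of 22, with a mean of -0.001, and Bcl2l11, the gene of the cell death activator BIM, differed by -0.35 (SE 0.10) and Mdm2 by 0.16 (SE 0.06). That list did not pass either, with an adjusted p of 0.60 in limma camera with Benjamini-Hochberg adjustment. In these 3 lists 0 genes passed in limma, adjusted over the list alone or over all genes, and 2 apoptosis genes had an unadjusted p under 0.05.

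Adipocyte markers stood apart among the remaining cell types. All 8 tested markers were lower, with a mean log2 difference of -0.87, and the list fell in camera (adjusted p = 5.3e-05, limma camera, Benjamini-Hochberg over the lists), a call lost at adjusted p = 0.90 with an estimated correlation. The list means of IgG replicates 1 and 3 were 3.64 and 2.60 in log2(TPM + 1). Those of IgG replicates 2 and 4 were 1.52 and 1.76, within the anti-PD-L1 range of 1.29 to 1.83. The values of IgG replicate 1 weighed on it: Fabp4, a fatty acid carrier, was at 33.2 TPM there and at 1.24 to 9.26 TPM in the other IgG libraries, and the mean difference was -0.45 without that library and -1.33 with a pseudocount of 0.1. Adipoq, the gene of adiponectin, was at 6.59 ± 1.61 and 4.27 ± 0.873 TPM (SD, n = 4). Erythrocyte genes were higher in 5 of 5, with a mean of 0.57, and Hba-a2 differed by 0.89 (SE 0.72), or by 1.64 without IgG replicate 1 and 0.54 without anti-PD-L1 replicate 3. That list passed without IgG replicate 1, with a mean of 1.14 (adjusted p = 1.0e-04, limma camera, Benjamini-Hochberg over the lists), a call lost at adjusted p = 0.76 with an estimated correlation. Endothelial markers were lower in 7 of 10 with a mean of -0.06, among them Vwf by -0.27. The endothelial list passed with no filter (mean -0.09, adjusted p = 0.024) and with rescaling over protein-coding genes (mean -0.08, adjusted p = 0.029) in limma camera with Benjamini-Hochberg adjustment. Both calls were lost with an estimated correlation, at adjusted p = 0.83 and 0.73. Smooth muscle and peritubular myoid markers were lower in 9 of 11 with a mean of -0.04, among them Acta2 by -0.08, or by -0.04 without either anti-PD-L1 replicate 1 or 3 and -0.13 without anti-PD-L1 replicate 4. Fibroblast and extracellular matrix genes were higher in 8 of 15, with a mean of 0.01 against a downward direction in camera, and Postn differed by 0.17, or by 0.11 without anti-PD-L1 replicate 3. Of 4 tested epididymis markers 2 were higher, too few for a list test. The mean of the 13 members with a mean above 0 TPM, tested or not, had an exact permutation p of 1.00. Defb21 differed by -0.38. Without anti-PD-L1 replicate 4 that value was -0.15, without anti-PD-L1 replicate 3 it was -0.63, and without IgG replicate 3 it was -0.58. The median of the 4 tested epididymis markers was 0.006 and their mean -0.03. In the test as designed adjusted p was 0.29, 0.26, 0.29 and 0.87 for the erythrocyte, endothelial, myoid and fibroblast lists in limma camera with Benjamini-Hochberg adjustment.

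Genes of cytosolic ribosomal proteins were lower in 33 of 40, with a mean of -0.04, and the list fell in camera (adjusted p = 0.0063, limma camera, Benjamini-Hochberg over the lists). The call was lost at adjusted p = 0.90 with an estimated correlation and without IgG replicate 1, anti-PD-L1 replicate 1 or anti-PD-L1 replicate 3, and the mean was 0.008 without IgG replicate 1, -0.07 without anti-PD-L1 replicate 4 and -0.08 with TMM rescaling. Rps20 differed by -0.25 (SE 0.09), or by -0.16 without IgG replicate 1. Immediate-early genes were higher in 8 of 12, with a mean of 0.11, and Dusp1 was at 8.08 ± 2.07 and 12.7 ± 2.75 TPM (SD, n = 4). Of the heat shock and unfolded protein response genes 13 of 20 were higher, with a mean of 0.04, and the small heat shock gene Hspb1 differed by 0.83 (SE 0.25). Oxidative stress genes were higher in 13 of 19, with a mean of 0.04, among them Gclm by 0.16. Mitochondrially encoded genes were higher in 11 of 13, with a mean of 0.22, and mt-Atp6 differed by 1.06, or by 0.40 without IgG replicate 2, 1.58 without IgG replicate 1 and 1.68 with array quality weights. The mitochondrial list passed without IgG replicate 1, with a mean of 0.35 (adjusted p = 0.021, limma camera, Benjamini-Hochberg over the lists), a call lost at adjusted p = 0.76 with an estimated correlation. In the test as designed adjusted p was 0.29, 0.94, 0.60 and 0.55 for these last 4 lists in limma camera with Benjamini-Hochberg adjustment. Across these context lists 0 genes passed in limma, adjusted over the list alone or over all genes, and 1 adipocyte, 1 ribosomal, 2 immediate-early and 1 heat shock gene had an unadjusted p under 0.05.

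In total 23 of the 26 lists could be tested, and camera with its preset correlation called 4 of them. Camera with an estimated correlation called 0, and fry called 0 with a smallest adjusted p of 0.769 (limma, Benjamini-Hochberg over the lists). Exact permutation used list means over members with a mean above 0 TPM, tested or not. It gave an unadjusted p of 0.114 for the adipocyte list (12 members, difference -0.68) and 0.171 for the elongating spermatid list, and 0 of 26 lists were under 0.05. Since its smallest possible p, 0.0286, would not pass for a single list after adjustment over 26 lists, permutation could not test these calls one by one. A filter of 5 TPM left 16 lists with enough members to test and 2 calls. The spermatogonia list lost its call there, while the adipocyte list had too few members left and was not tested. Of the 19 lists not called, 6 passed under at least 1 alternative, and the mean of each of the 19 moved by over 1.5 times or changed direction when 1 library was left out. Small shifts reach that factor where a mean is near 0. The means of the called adipocyte and ribosomal lists moved by as much or changed direction as well.

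**Figure D2:**
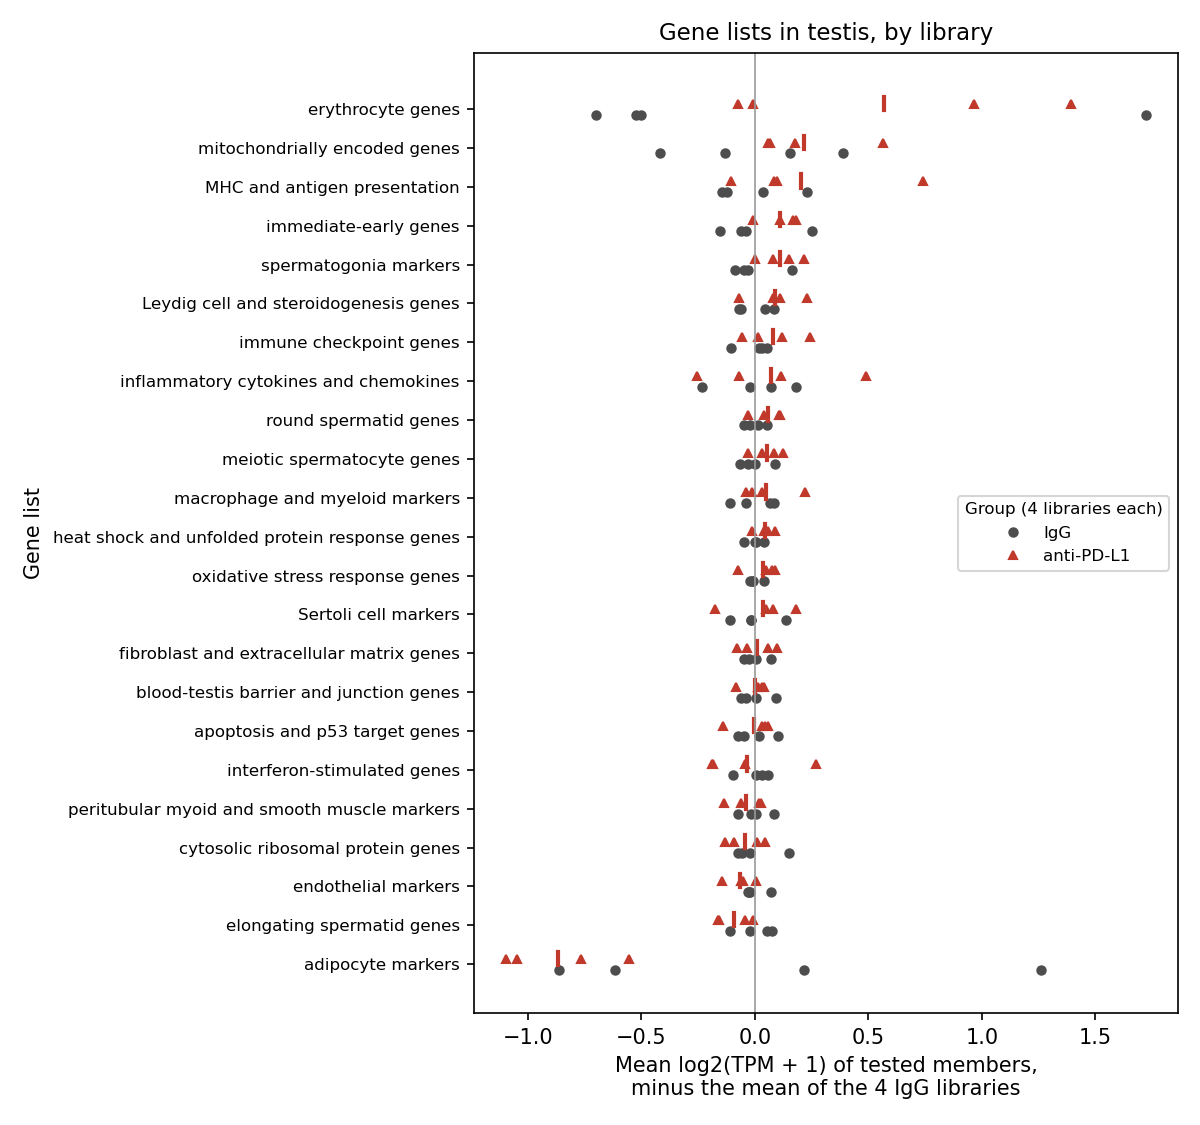
Mean log2(TPM + 1) of the tested members of 23 gene lists in each library, as the difference from the mean of the 4 IgG libraries, with the mean of the 4 anti-PD-L1 libraries as a vertical line. The adipocyte list had the lowest mean difference, -0.87, and single libraries lay far from their group in the adipocyte, erythrocyte and MHC lists.

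The libraries did not separate by treatment along the main axis of variation. IgG replicate 4 and anti-PD-L1 replicate 1 lay apart from the other 6 on a component that held 32.2% of the variance. These 2 libraries correlated at 0.966 with each other across genes and at 0.955 to 0.963 with the other 6, which correlated at 0.970 to 0.979 among themselves, and genes are not independent replicates. The nuclear noncoding RNA Malat1 was at 82.9 and 101 TPM in these 2 libraries and at 8.16 to 20.6 TPM in the other 6. Without both, a choice made after seeing the data, 8 genes passed in limma with Benjamini-Hochberg adjustment, and 5 lists were called, the 4 above and interferon-stimulated genes, which were then lower by a mean of -0.12 (adjusted p = 0.035, limma camera, Benjamini-Hochberg over the lists). With an estimated correlation all 5 calls were lost, at adjusted p = 0.73 for interferon-stimulated genes, spermatogonia, elongating spermatids and adipocytes and 0.98 for ribosomal proteins (limma camera, Benjamini-Hochberg over the lists).

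**Figure D3:**
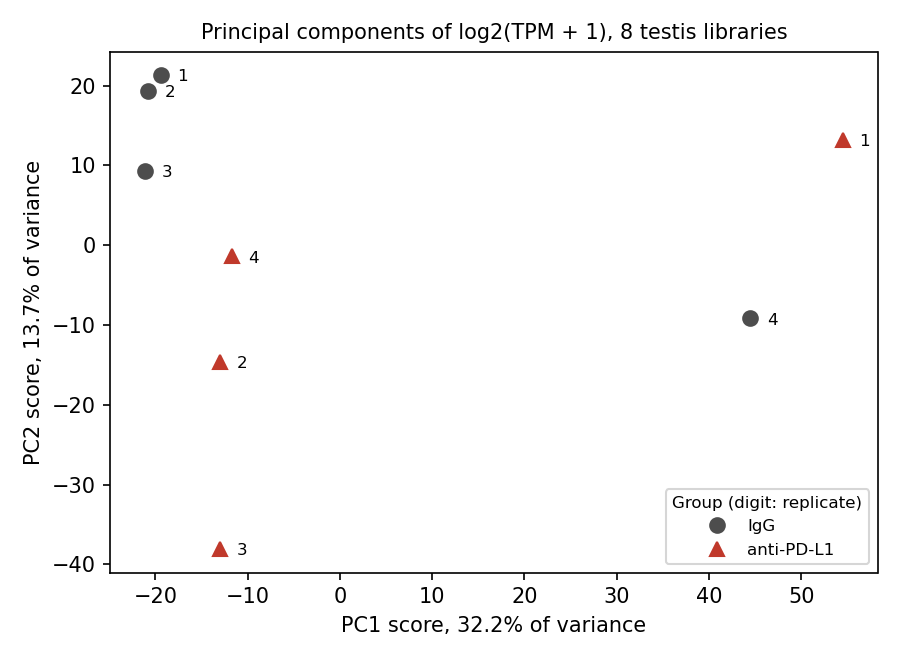
Scores of the 8 testis libraries on the first 2 principal components of log2(TPM + 1), with the replicate number beside each point. IgG replicate 4 and anti-PD-L1 replicate 1 lay apart from the other 6 libraries on the component that held 32.2% of the variance.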

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

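Tests of unspliced or nuclear RNA in the libraries that stand apart, the use of the value without IgG replicate 1 to weigh fat tissue, and the counts among splits that part those libraries were chosen after the results were seen, and the other tests in this part were written before. A library was singled out here when its gap to the nearest of its group exceeded 0.829 of the group's range, which chance gives in about 1 of 20 groups. Of 170 groups 18 were singled out, where chance gives about 8.5 for independent groups. The groups overlap, as a gene and its list do, and several measures repeat the 2 libraries that stand apart. The excess is therefore no test.

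IgG replicate 4 and anti-PD-L1 replicate 1 stood out in the same measures. Genes at 1 TPM or more numbered 21116 and 21083 in these libraries and 19494 to 19665 in the other 6, with gaps of 0.924 and 0.946 of the range. Malat1 gaps were 0.834 and 0.913, and Neat1, at 32.8 and 36.1 TPM against at most 10.8 TPM in the other 6, had gaps of 0.921 and 0.901. Unannotated loci held 1.81% of TPM in anti-PD-L1 replicate 1 and 1.19% to 1.29% in the rest of its group, a gap of 0.844. A smaller share of germ cells would raise all somatic lists in these libraries and cannot be told apart: medians were 0.14 for macrophage, 0.07 for Sertoli, 0.06 for endothelial, 0.02 for myoid and -0.015 for Leydig cell genes, the last with a bootstrap range from -0.13 to 0.12 that overlaps those of the other 4. More RNA without a poly(A) tail cannot be told apart either. For it, 24 replication-dependent histone genes were higher by a median of 0.10, with a bootstrap range from -0.04 to 0.28. For both explanations the tested median lay under the bound written beforehand against them. The bootstrap ranges were not part of those bounds and reach past them, so neither explanation is decided. More nuclear or unspliced RNA stays open: noncoding genes and unannotated loci held at least 6.64% of TPM in both libraries against at most 6.35% in the other 6. No biological explanation other than the share of germ cells was tested, and the pair holds 1 library of each treatment.

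IgG replicate 1 was high in 5 measures. Hba-a2 was singled out with a gap of 0.961, the erythrocyte list with 0.918, the endothelial list with 0.912, Ighm with 0.871 and Gbp3 with 0.833. Its adipocyte mean was the highest of its group and was not singled out. For the lower adipocyte list, fat taken along with some IgG testes and a loss of adipocyte transcripts after anti-PD-L1 cannot be told apart. In that library 6 of 8 markers (75%) were at least 2 times the anti-PD-L1 median, but it is also the library with the highest adipocyte mean, so this restates the pattern. The ratios were uneven, at 296 for Car3, 117 for Cfd and 26.6 for Fabp4, against 2.15 for Adipoq, 1.59 for Plin1 and 1.32 for Cidea. Without that library the mean difference was -0.45 and the list still passed (adjusted p = 0.0060, limma camera at the preset correlation, Benjamini-Hochberg over the lists), a call lost at adjusted p = 0.76 with an estimated correlation. Among the IgG libraries then left, only replicate 3, with a list mean of 2.60, lay above the anti-PD-L1 range of 1.29 to 1.83.

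Anti-PD-L1 replicate 1 was high for Ccl8, Cd74 and H2-Aa, with gaps of 0.910, 0.899 and 0.864. Taf12 was high in IgG replicate 2, with a gap of 0.877. Hspb1 was low in IgG replicate 3, with a gap of 0.848. The apoptosis and p53 list was low in anti-PD-L1 replicate 3, with a gap of 0.852.

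With 0 genes past the threshold in the real split, all 35 splits of the 8 libraries into groups of 4 reach that count by construction, so it cannot be set against chance, and the highest of the others gave 4. Chance could not be excluded for the other counts. At an unadjusted p under 0.05, 14 of 35 splits gave at least the 1063 genes of the real split, and the highest other gave 3194. That points to a structure of the samples that the real split follows at most in part, as it too keeps IgG replicates 1 to 3 together. The 3 highest, at 3194, 2027 and 1969, set IgG replicates 1 to 3 and 1 of anti-PD-L1 replicates 2 to 4 against IgG replicate 4 and the other 3 anti-PD-L1 libraries. Of these 14, 12 kept the 2 libraries that stand apart together, and of the 20 splits that part them, as the real one does, 2 gave as many, the real one and 1 with 1297. For gene lists 22 of 35 splits gave at least the 4 of the real split, and the highest other gave 9. Among the 20 splits that part those libraries, 13 gave at least 4. The 15 splits that kept the 2 libraries that stand apart together had a median of 1317 genes at an unadjusted p under 0.05, against 568.5 in the splits that parted them.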

How the results depend on the processing

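Results without both libraries that stand apart, with rescaling over protein-coding genes, with GC and length removal, with a covariate and with permuted list means were chosen after seeing the data. The count of 0 genes held under 11 of 20 alternatives and was 1 with a pseudocount of 0.1 (Gm49462), 5 with array quality weights, 8 without both libraries that stand apart, 1 over protein-coding genes (Gm9887) and 1 after GC and length removal (Gm9887). Leaving out each library gave 0 to 15 genes and 3 to 5 lists. The 4 lists became 2 at 5 TPM, where fewer genes were tested and the adipocyte list could not be tested. They became 0 with an estimated correlation and 0 with fry. Permuted means gave 0 too, which decides nothing, since a single list at the smallest p they can give would not pass after adjustment. For elongating spermatid genes the mean was -0.11 without both libraries and ranged from -0.13 to -0.05. The ribosomal list lost its call under quantile normalization, array weights and GC removal, and the spermatogonia list with the covariate and over protein-coding genes. Of the 19 lists not called 6 gained a call, antigen presentation under 5 alternatives, interferon-stimulated and endothelial under 2 each, and round spermatid, erythrocyte and mitochondrial under 1 each. With an estimated correlation 0 lists passed under these settings, with a smallest adjusted p of 0.58. Cd274 stayed between 0.10 and 0.26 and did not pass in any. Of 1007 values for 51 named genes 1002 kept direction and side of the threshold, and 4 came to pass. These genes were picked by small p in the same data and none passed in the test as designed, so this count does not measure robustness. Ighm ranged from -0.26 to 0.010 over left-out libraries, turning without IgG replicate 1. The cause of these changes was not tested. Replicate numbers did not pair the libraries: same-numbered libraries correlated at -0.11, 0.10, 0.09 and -0.20 in their deviations, and the replicate block gave 0 genes and 5 lists, the 4 and antigen presentation (adjusted p = 0.019, limma camera, Benjamini-Hochberg over the lists; 0.80 with an estimated correlation), and changed no other call. Unknown depth limits how firmly low genes can be read.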

Other observations

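All tests of hypotheses in this part were chosen after the result was seen. Of 2081 Gene Ontology terms with 10 to 500 genes, 0 passed in camera, with a smallest adjusted p of 0.70 in limma camera with Benjamini-Hochberg adjustment and 130 terms at an unadjusted p under 0.05. Without the 2 libraries that stand apart 0 passed as well, with a smallest adjusted p of 0.33 in the same test.

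Without the 2 libraries that stand apart, genes named here after their values were seen include Thoc3, a subunit of the THO messenger RNA export complex, at 18.0 to 18.4 TPM in IgG replicates 1 to 3 and 32.5 to 35.1 TPM in anti-PD-L1 replicates 2 to 4. In the libraries left out it was at 33.2 TPM in IgG replicate 4 and 33.0 TPM in anti-PD-L1 replicate 1. The histone variant gene H2al1d was at 5.65, 10.2 and 6.75 TPM in IgG replicates 1 to 3 and listed at 0 in the other 5 libraries, IgG replicate 4 among them. The pseudogene Gm6565 was at 25.4, 18.1 and 12.3 TPM in the same 3 libraries and listed at 0 in the other 5. Gm2005 was at 1.22 TPM in IgG replicate 4, 0 in the other IgG libraries and 1.11 to 2.48 TPM in the anti-PD-L1 libraries. The remaining genes that passed did not all place IgG replicate 4 with the anti-PD-L1 libraries. Gm12751 was at 39.45 TPM there, 37.8 to 48.7 TPM in the other IgG libraries and 0 to 16.8 TPM in the anti-PD-L1 libraries. Gm49462 was at 3.19 TPM in IgG replicate 4 and listed at 0 in all anti-PD-L1 libraries. An unannotated locus was at 10.4 TPM there, at most 2.06 TPM in the other IgG libraries and 47.3 to 108 TPM in the anti-PD-L1 libraries. Gm42959 was at 8.72 TPM in IgG replicate 4 and 6.41 to 10.3 TPM in anti-PD-L1 replicates 2 to 4. It was listed at 0 in the other IgG libraries and in anti-PD-L1 replicate 1. Genes that share reads with close copies, as multigene histone families and pseudogenes do, are uncertain here.

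A hypothesis is that the library labelled IgG replicate 4 carries the wrong group label, since leaving it out gave 15 genes, more than leaving out any other single library. It was placed between the group means (0 for IgG, 1 for anti-PD-L1) over the 100 genes that best parted 3 IgG from 3 anti-PD-L1 libraries chosen without it, with each anti-PD-L1 library left out in turn. Its median position was 0.592 to 0.776, above the highest of the other IgG libraries, 0.410, and the anti-PD-L1 libraries placed in the same way lay from 0.409 to 0.937. The position fell between the bounds set for and against a wrong label, and this library also shares the profile of anti-PD-L1 replicate 1, so the explanations cannot be told apart, and the labels were used as given. An exchange of labels between these 2 libraries was not tested on its own: the split that makes it gave 2 genes, 7 lists and 1297 genes at an unadjusted p under 0.05, against 0, 4 and 1063 for the real split. On the second component, with 13.7% of the variance, IgG replicates 1 to 3 and anti-PD-L1 replicate 1 scored 9.35 to 21.3 and the other 4 libraries -38.1 to -1.40, while anti-PD-L1 replicate 1 had a median position of 0.623 by the held-out genes, within the range of the other anti-PD-L1 libraries.

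Insl3 differed by 1.30 on the log2 scale, while the other Leydig cell genes had a median of -0.011 (n = 18, bootstrap range -0.06 to 0.09), although Fdx1 among them was also higher, by 0.57. A larger share of Leydig cells would raise them all by about as much as Insl3, so the median argues against it. Reads moved from the overlapping Jak3 gene are argued against by its size: the highest IgG value of Jak3, in TPM times length, was 2.45% of the gain of Insl3. The libraries that stand apart do not account for it either, since the log2 difference without them was 1.09 times that with all 8. A change of Insl3 transcripts in Leydig cells after anti-PD-L1 remains a hypothesis that may also be chance, as its adjusted p was 0.202 in limma with Benjamini-Hochberg adjustment and 0.0710 to 0.910 over the alternatives.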
